A study of Saccharomyces cerevisiae with 2 samples.

How the data were processed

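The series holds 2 libraries of 1 budding yeast strain (yJC2229, Saccharomyces cerevisiae), 1 of total RNA and 1 of ribosome footprints, each with replicate number 1. Per the labels' protocols, cells grew at 24 °C in YPD, a rich glucose medium, and were taken in mid-log phase with no pretreatment. Cycloheximide, a drug that stops elongating ribosomes, was present during lysis. Footprints, the mRNA fragments that a ribosome protects from nuclease, came from the 80S part of a sucrose gradient, and total RNA was broken up with alkali. Ribosomal RNA was depleted with Ribo-Zero before cDNA libraries were made and amplified. The submitters' processing notes name cutadapt, Bowtie2, HISAT2 and HTSeq and the sacCer3 genome build. Their versions, order and settings, the read lengths kept, the use of strand, the handling of reads that match several genes and the removal of PCR duplicates are not given in the sources used here.

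A table of genes by codons was used, with 4579 genes and 3 kinds of columns. The deposited footprint columns hold raw counts for each of the 64 codons in each gene, summed over all places where the gene has that codon, per the file headers. Which ribosomal site the authors assigned to the counted codon is not stated. A further 64 columns carry a header word that can be read as total RNA, but their values are the number of times each codon occurs in the coding sequence: 4575 genes have 1 stop codon in them and 4 genes have 2, and 0 pairs of gene and codon have footprints without an occurrence. The deposited abundance column is headed FPKM, with no library named. Its values behave as CPM values (counts scaled to a fixed library total) that the authors did not divide by gene length, since 100% of them are whole multiples, within 0.001 reads, of a single step of 0.0459 CPM. The step corresponds to 21771294 reads of 1 library, of which 21353772 (98.1%) lie in the listed genes, and it was used to turn each value into reads. Gene symbols came from a RefSeq gene table of assembly R64, which the UCSC browser calls sacCer3. It matched all but 1 of the gene identifiers, and coordinates are from that table.

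Several parts of the planned design had no values to run on. RNA counts per codon, and counts by position within a gene, are not analysed here, so codon values were not divided by a total RNA value, the first and last codons of genes were not left out, and profiles along the reading frame and the evenness of counts along genes were not computed. The codon value used in their place is the number of footprints per occurrence of a codon divided by the mean footprints per codon of the same gene, averaged over all occurrences, so that 1 is the level of an average codon of the gene. The footprint to read ratio of a gene is its share of all footprints divided by its share of the reads behind the abundance column. It equals the usual translational efficiency only if that column was made from the total RNA library.

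Codon values and gene ratios used the 2939 genes with at least 100 footprints and 100 reads. These genes hold 97.5% of the footprints. Ratios carry exact conditional binomial (Clopper-Pearson) 95% intervals, which cover counting error only. Codon values carry 95% intervals from 1000 resamples of genes, which describe variation among genes of 1 library and not between cultures. Gamma intervals for counting error alone were computed beside them. Amplified reads without molecular identifiers are not independent molecules, and codons that occur once in a gene varied more than counting allows: the variance of their footprints was 7.47, 9.54 and 21.7 times the mean in genes with gene means of 0.8 to 1.6, 1.6 to 3.2 and 3.2 to 6.4 footprints per codon. These figures pool different codons and genes, so they also hold differences between codons and between gene means. They do not measure amplification alone. With 1 library per group there is no replicate check, and no p-value was computed. Lists were fixed before the data were examined: 18 gene lists and 11 codon lists. A gene list's median log2 ratio was placed among 10000 random lists of the same size, matched on reads in 20 bins. A codon list's mean was placed among 10000 random codon lists of the same size. Both percentiles describe these libraries. After the data were seen, matching on coding length was added, and so were a straight line and then a smooth trend (LOWESS, 30% of the genes) of the ratio on length. Intervals of correlations and slopes across genes are from resampled genes, which are not independent replicates.

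Named genes followed a rule set before the data were examined: the 12 highest and 12 lowest ratios, the highest and lowest tested member of each list, and the 8 genes with the most counts in each library. Named codons were the 5 highest and 5 lowest sense codons, CGA and the proline codons. Other genes and codons named in the text were chosen after their values were seen. Genes were treated as near-identical when their codon counts differed by at most 5% of codons and their lengths by at most 2%. Reads of such genes, and of other paralogs, cannot be assigned with certainty. In simulated data drawn from the read counts of 2747 genes, genes given a ratio of 2 log2 units had a median estimate of 2.00. Those given -2 had -2.00 and those given -1 had -1.00. The count minimum was reached by 50 genes given 2 and 49 given 1, but by 39 given -1 and 26 given -2. It thus left out more genes of low ratio than of high ratio. The ratio intervals held the simulated value in 95.4% of 1500 genes, and no codon value was off by more than 3.16%. The simulated counts had counting error alone, without the extra variance of the real counts. These figures therefore check the computation and not the accuracy of values in these libraries. Of 100 unrelated gene lists 7 fell outside the middle 95% of random lists. Alternatives covered scaling, count minimums, stop codons, overlapping and near-identical genes, weighting, caps on high counts and the reading of the abundance column. Computations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and Matplotlib 3.10.9.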

Results

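The series title names ribosomal elongation rate, predicted from ribosome profiling, as its subject. Ribosome footprints and total RNA of 1 yeast strain were sequenced, with 1 library of each kind. The footprint library contributed 3756929 footprints over 2292688 codon occurrences in 4579 genes, or 1.64 footprints per occurrence. A gene had between 25 and 79140 footprints, with a median of 157. Of the pairs of gene and codon with at least 1 occurrence, 40.4% held no footprint. The authors' abundance column corresponds to between 6 and 476811 reads per gene, with a median of 1457. Glycolytic and fermentation enzymes and cell surface or antioxidant proteins led the footprints: FBA1 (79140 footprints), CCW12 (71657), ENO2 (66454), PDC1 (66082), CDC19 (64743), TDH3 (62743), AHP1 (40649) and ADH1 (38966) together took 13.1%. The 8 genes with the most reads, at 11.4% of reads, were PDC1, CDC19, TDH3, YEF3, ENO2, FBA1, PMA1 and PGK1.

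The first comparison asked how ribosome occupancy differed between codons. CCG, a rare proline codon, held the most footprints of any sense codon, at 4.80 times the mean codon of its own gene (95% interval over genes 4.58 to 5.04). The arginine codon CGA, which yeast reads by inosine-adenine wobble, followed at 3.76 (3.45 to 4.09), then the leucine codon CTG at 2.61 (2.51 to 2.71), the arginine codon CGG at 2.57 (2.24 to 2.96) and the proline codon CCC at 2.28 (2.17 to 2.39). The lowest values belonged to the glutamine codon CAA at 0.620 (0.597 to 0.640), the valine codons GTT at 0.647 (0.619 to 0.676) and GTC at 0.690 (0.657 to 0.725), and the phenylalanine codons TTC at 0.682 (0.650 to 0.713) and TTT at 0.684 (0.656 to 0.714). CCG stood 7.75 times as high as CAA (7.29 to 8.27), an interval that leaves out the choice of method. The fold between the highest and lowest sense codon was 3.35 with high counts capped at the 90th percentile. It was 12.6 for counts pooled over all 4579 listed genes (GCT over AAT), which changes the gene set as well. Medians over genes could be had for 55 sense codons, without CCG, CGA, CGG, CGC, CTC and TGC. They used only genes with 1000 or more counts and 5 or more occurrences of the codon. Over these codons CTG was 4.58 times CAA, against 4.21 for the means, which used all 2939 genes. Of the 61 sense codons, 26 lay above 1 and 24 below 1 by more than their intervals over genes.

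Synonymous codons of proline had the largest fold, with an interval that overlaps that of arginine. CCG was 4.03 times CCA (3.79 to 4.28), the codon of this family that highly expressed yeast genes use, and CCT lay between them at 1.76 (1.70 to 1.82), while CCA was at 1.19 (1.15 to 1.24). Arginine followed, with CGA at 3.84 times CGT (3.40 to 4.33), and leucine, with CTG at 3.51 times TTA (3.31 to 3.70). Isoleucine ATA was 2.18 times ATT (2.07 to 2.29) and alanine GCG was 2.12 times GCT (2.01 to 2.27). Both asparagine codons had the same value within their interval (AAC 0.694, AAT 0.694), as did both phenylalanine codons. As families, proline codons averaged 1.89 over their occurrences, and phenylalanine (0.683), asparagine (0.694) and glutamine (0.708) codons were the lowest.

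**Figure D1:**
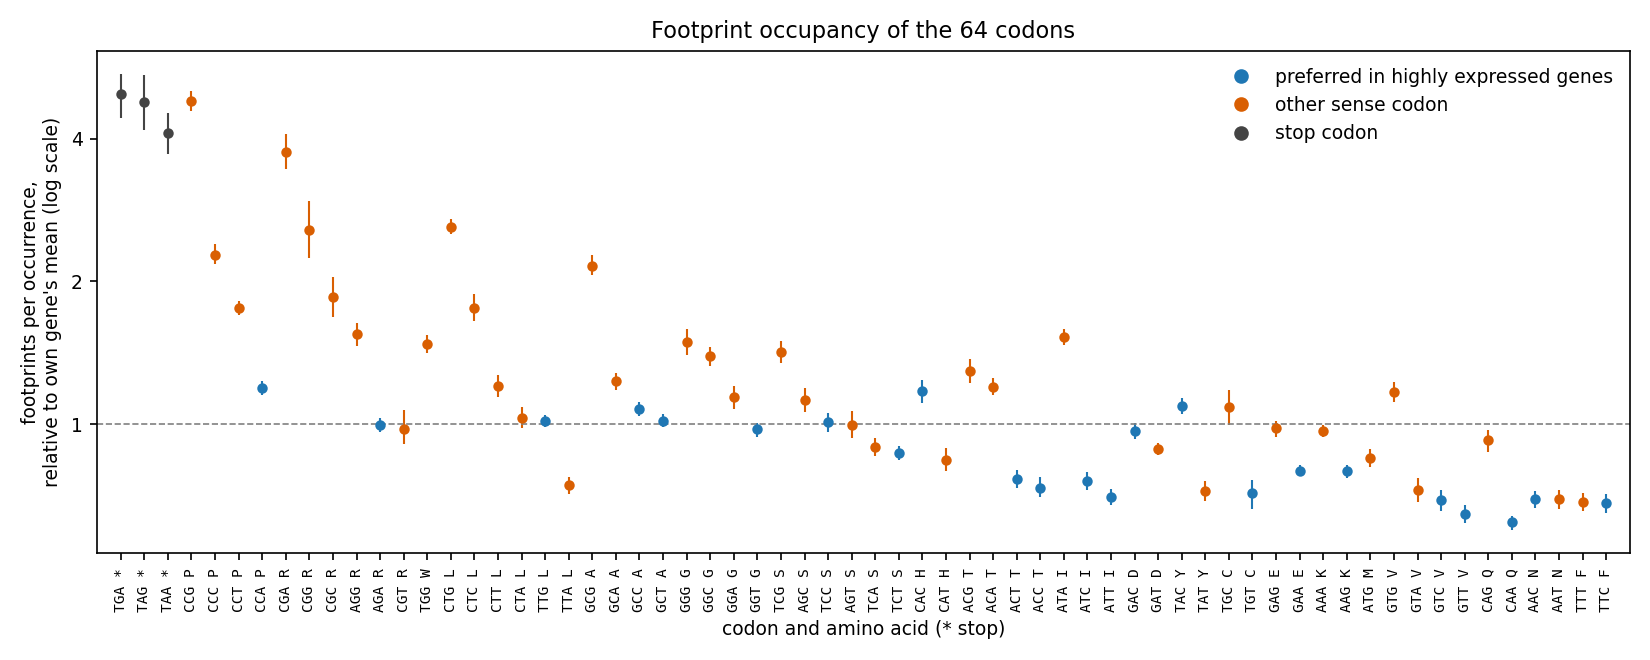
Footprints per occurrence of each of the 64 codons relative to the mean codon of its own gene (vertical axis, log scale), grouped by amino acid (* marks stop) and coloured by whether the codon is preferred in highly expressed yeast genes. Bars are 95% intervals over genes of the 1 footprint library. CCG reaches 4.80 and CAA lies at 0.620.

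The 23 codons preferred in highly expressed yeast genes averaged 0.869, against 1.44 for the other 38 sense codons. The difference of -0.572 (-0.592 to -0.553 over genes) lay at percentile 0 of random codon lists. It was -0.251 with high counts capped at the 90th percentile, and turned to 0.957 for counts pooled over all listed genes. Of the preferred codons, 13 lay below 1 by more than their intervals and 4 above, CCA and CAC being the highest of these at 1.19 and 1.17. Over all listed genes, tested or not, the preferred codons made up 47.4% of occurrences and received 70.2% of the footprints. The footprint means of the genes that hold them would give 74.4%. Proline codons averaged 2.51 without weighting by occurrence (percentile 99.5) and the CGN codons of arginine 2.29 (percentile 98.5). For pooled counts the CGN list differed from the other codons by -0.20. Glycine codons averaged 1.25, which differed from the other codons by 0.0236 (-0.0145 to 0.0620), so no difference was detected. Aspartate and glutamate codons averaged 0.907 (percentile 14.5) and the lysine, arginine and histidine codons 1.55 (percentile 91.7). Codons ending in G or C averaged 1.40 and those ending in A or T 1.04 (percentile 97.6).

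Pairs of codons read by the same tRNA were compared to ask whether wobble pairing went with more footprints. Only pairs on the fixed codon lists were compared. Among the 8 listed pairs read by a tRNA with G at its wobble base, the C form, which pairs by Watson-Crick rules, was higher in 6 pairs, and the T form in 0. The largest ratios of C form over T form were those of cysteine (TGC over TGT 1.52, 1.36 to 1.70), tyrosine (TAC over TAT 1.51, 1.42 to 1.60), glycine (GGC over GGT 1.43, 1.34 to 1.51) and histidine (CAC over CAT 1.40, 1.30 to 1.50). Over the 8 pairs the C form exceeded the T form by 0.212 (0.184 to 0.238), by 0.134 with the 90th percentile cap and by 0.490 for pooled counts. As whole lists, the C forms averaged 1.03 (percentile 21.3) and the T forms 0.814 (percentile 0.44). Among the 6 listed pairs read by an inosine tRNA, the C form was higher in 4, led by arginine CGC over CGT at 1.89 (1.68 to 2.15), and the mean difference was 0.191 (0.152 to 0.228). Without the arginine pair the difference was 0.0542 (0.0316 to 0.0752), and over all inosine pairs it was 0.0601 with the 90th percentile cap, 0.0631 for pooled counts and, over the 5 pairs without arginine, 0.0370 for medians over genes. The T forms averaged 0.830 (percentile 1.61) and the C forms 1.02 (percentile 26.1). In both sets the C form of a pair also holds more G and C bases than the T form. Over the sense codons, values rose with the number of such bases (Spearman rho 0.671). The kind of pairing and the base content therefore cannot be told apart in these pairs.

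**Figure D2:**
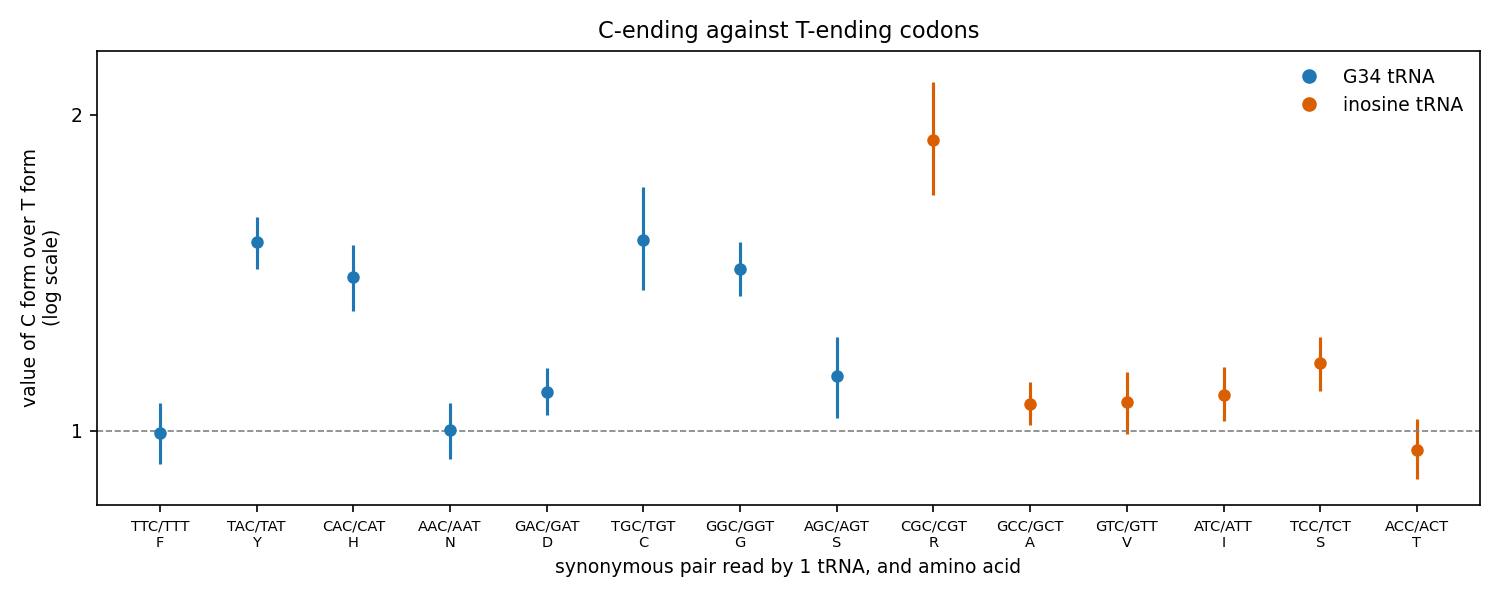
Value of the C-ending codon over that of the T-ending codon (vertical axis, log scale) for the synonymous pairs on the fixed G34 and inosine lists. Points are ratios and bars 95% intervals over genes. The T form is not above the C form by more than its interval in any of the 8 G34 or 6 inosine pairs.

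Stop codons held more footprints than the mean codon of their gene: 4.11 times for TAA (3.72 to 4.52), 4.79 for TAG (4.18 to 5.44) and 4.96 for TGA (4.42 to 5.49). The medians over genes were lower, at 1.53, 1.84 and 1.98. About 1 gene in 3 had no footprint on its stop codon, with shares of 34.8% for TAA, 34.4% for TAG and 35.7% for TGA. In the 154 genes with a single ATG, which is then the start codon, that ATG held 0.0561 times the gene mean (0.0249 to 0.0993). These codon results depend on setting each gene's counts against its own mean. With counts simply pooled over all 4579 listed genes, which lets highly translated genes dominate, the preferred codons exceeded the others by 0.957. CGA (0.593), CGG (0.463), CTG (0.845) and CCC (0.837) then fell below 1, and GTC (1.96), GTT (1.21) and TTC (1.04) lay above 1. Pooling over the tested genes alone was not run, so a part of these changes can come from the gene set. With every listed gene and the gene means kept, the preferred-codon difference was -0.598. Counts of total RNA per codon were not used here, so preferences of library preparation for certain sequences were not divided out.

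The second comparison set each gene's share of footprints against its share of the reads behind the authors' abundance column, to ask how unevenly ribosomes were spread over mRNAs. The header of that column names no library, which limits every ratio below. Among 2939 genes the SD of the log2 ratio was 1.07 (1.04 to 1.10), and the 10th and 90th percentiles were ratios of 0.329 and 2.14, a 6.51-fold range. Across genes, footprints per codon and reads per codon had a Spearman rho of 0.801 (0.784 to 0.815). The highest ratio was that of PXR1 (YGR280C, chromosome VII, 1050910 to 1051725, sacCer3), a nucleolar protein of rRNA and snoRNA maturation, with 321 footprints and 229 reads and a ratio of 7.97 (6.70 to 9.48). LSM3 (6.13), RPL37A (5.67), LSO2 (5.43), VPS24 (5.32), FYV4 (5.29), FYV7 (5.07), ADF1 (4.98), MIC10 (4.95), IES2 (4.88), MRP2 (4.78) and ACM1 (4.58) came next. RPL37A, a large subunit ribosomal protein, had 11824 footprints, while the other 10 of these had between 128 and 593, and ADF1 overlaps FYV5. Among the genes tested, the lowest ratio was that of REA1 (YLR106C, chromosome XII, 349006 to 363738), the giant ATPase of 60S subunit assembly. It had 123 footprints, 24369 reads and a ratio of 0.0287 (0.0238 to 0.0342). UTP20 (0.0408), TOM1 (0.0441), BLM10 (0.0528), VPS13 (0.0587), UBR1 (0.0607), GLT1 (0.0623), GCN1 (0.0646), UTP10 (0.0647), NUP192 (0.0663), URB1 (0.0770) and CDC39 (0.0784) followed.

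The 12 lowest of the genes tested were 1684 to 4911 codons long and the 12 highest 90 to 321. The minimum of 100 footprints leaves out lower ratios, such as that of HAC1 (240 codons, ratio 0.00720). Over all genes tested, the ratio and coding length had a Spearman rho of -0.853 (-0.866 to -0.840 over genes), and the log2 ratio changed by -0.89 for each doubling of length. The median log2 ratio was 1.21 in genes of up to 100 codons, 0.97 from there to 200, 0.43 to 300, -0.18 to 500, -0.96 to 1000 and -2.34 above 1000 codons. Within each of 4 equal classes of read density, from low to high, the rho was -0.830, -0.870, -0.843 and -0.852. Footprints per codon went with length more (rho -0.661) than reads per codon did (-0.243). The minimum of 100 counts acted mostly on footprints, which 2939 genes reached, against 4561 for reads. It sets a floor on footprints per codon that is higher in shorter genes. A part of this contrast, and of the rho within classes of read density, can come from that floor. Among genes with many counts, the translation elongation factor YEF3 (1045 codons) had a ratio of 0.262 and the proton pump PMA1 (919 codons) 0.390, against 2.89 for CCW12 (134 codons) and 3.08 for AHP1 (177 codons).

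**Figure D3:**
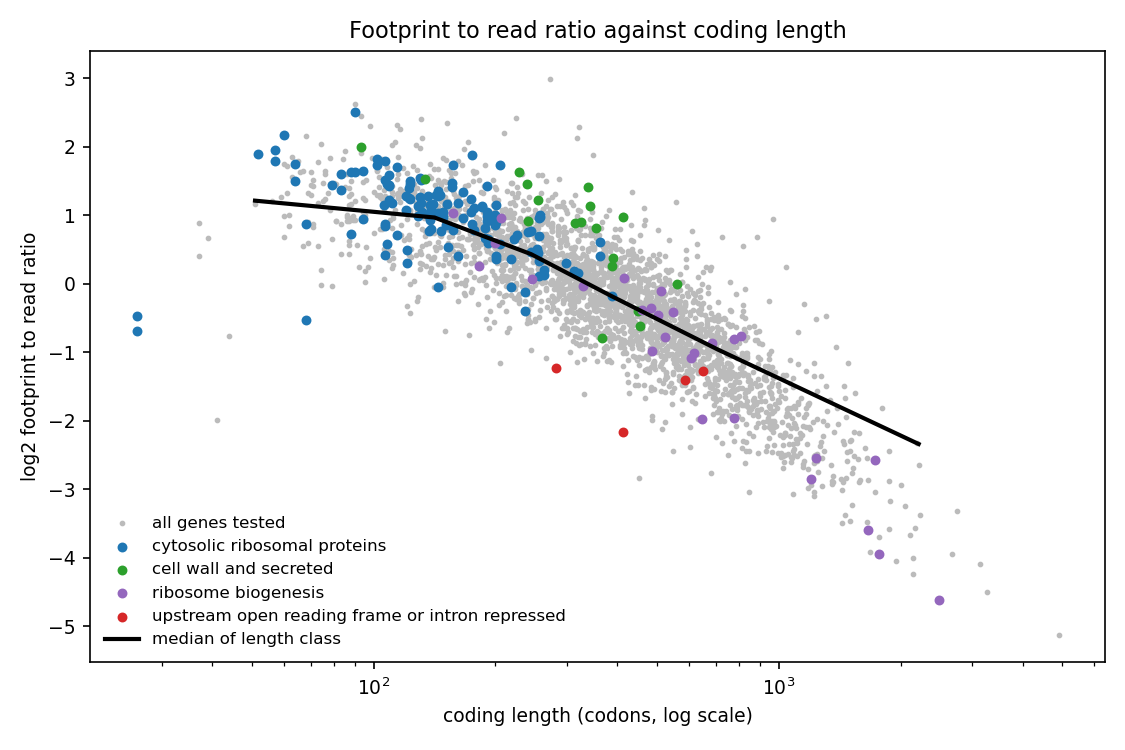
log2 footprint to read ratio (vertical axis) against coding length in codons (horizontal axis, log scale) for the 2939 genes tested, with 4 gene lists in colour. The line joins the medians of length classes, from 1.21 for genes of up to 100 codons to -2.34 above 1000 codons.

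Cytosolic ribosomal proteins had high ratios as a group: 133 of 138 lay above the median gene, the median log2 ratio was 1.00, and the list lay at percentile 100 of random lists matched on reads and at 99.5 of those matched on coding length. With a smooth trend on length subtracted it lay at percentile 76.8, inside the middle 95%. Its extremes were RPL37A at 2.50 and RPL41B at -0.69, the latter a 26-codon frame whose reads cannot be assigned with certainty between it and RPL41A (-0.48). Cell wall and secreted proteins had a median of 0.90 (percentiles 99.9 for reads and 100 for length), with 15 of 18 above the median gene, from CWP2 at 2.00 to UTH1 at -0.80. Their examples include the mannoprotein CCW12 (1.53), CIS3 (1.64), SED1 (1.41) and PIR1 (1.13). All 10 histone genes lay above the median gene (median 1.08, percentile 99.99), led by the H2B gene HTB1 at 2.13, with the H2A variant HTZ1 lowest at 0.58. Against lists of equally short genes the histones lay at percentile 55.4. Nuclear-encoded subunits of oxidative phosphorylation behaved in the same way, with a median of 0.67, 28 of 32 above the median gene, and percentiles of 100 for reads and 24.6 for length. They ranged from QCR10 at 1.84 to SDH1 at -0.97. Proteasome genes had a median of 0.25 (25 of 33 above the median gene, percentiles 99.98 and 93.9), from PRE7 at 0.85 to the large base subunit RPN2 at -1.91.

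Genes listed for repression by upstream open reading frames or, for HAC1, by an intron had ratios below 1. CPA1, a subunit of carbamoyl phosphate synthetase, was at -2.16, HOL1 at -1.41, YAP1 at -1.28 and the amino acid starvation regulator GCN4 at -1.23. The median of these 4 was -1.35 (percentile 10.9 for reads, 0.36 for length). The other 3 listed genes had under 100 footprints: CLN3 (91 footprints, 2600 reads, ratio 0.199), CAD1 (84, 801, 0.596) and HAC1, the unfolded protein response factor, with 28 footprints and 22100 reads (ratio 0.00720, 0.00478 to 0.0104). Cyclins had a median of -1.42 over the 4 tested (percentiles 2.92 and 0.14), CLN2 at -1.75, CLN1 at -1.58, CLB1 at -1.25 and CLB2 at -1.19, and the other 5 had under 100 footprints, so the median rests on the members with more footprints.

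Aminoacyl-tRNA synthetases, mostly long genes, had a median of -0.86 with 3 of 19 above the median gene (percentiles 3.51 for reads and 75.5 for length), from ILS1 at -2.53 to TYS1 at 0.09. Ribosome biogenesis factors had a median of -0.78 (8 of 27 above; 11.3 and 41.2), from UTP20 at -4.61 to NHP2 at 1.03. Elongation and termination factors spread from EFT1 at -3.04, whose reads cannot be separated with certainty from those of its twin EFT2, to the eIF5A gene HYP2 at 1.31, with a median of -0.47 (13.0 and 46.4). Initiation factors had a median of -0.45 (47.0 and 50.1), from GCD6 at -1.87 to TIF35 at 0.87. Chaperones had a median of -0.44 (18.9 and 96.1), from the disaggregase HSP104 at -0.88 to the small protein HSP12 at 1.57. Glycolytic and fermentation enzymes were split, with 10 of 20 above the median gene and a median of -0.09 (45.9 and 96.3), from PFK1 at -1.81 to TPI1 at 0.80. Amino acid biosynthesis genes had a median of -0.23 (70.4 and 89.1), from LYS2 at -1.82 to HIS3 at 1.20, which are also the extremes of the auxotrophic markers (median 0.19 over 6 genes, 83.6 and 77.0). Mitochondrial ribosomal proteins had a median of 0.37 (69.0 and 2.77), from MRP2 at 2.26 to MRP1 at -0.89 among those tested. Their place among lists matched on reads depends on the setting: percentile 100 with a minimum of 30 counts or none, and 0.67 with the smooth trend on length subtracted. The mating genes analysed, MFA1 at 0.89, MFA2 at 0.67, BAR1 at -0.29 and STE2 at -0.54, had a median of 0.19 (87.2 and 35.0). Mitochondrially encoded genes were not analysed here. Taking the abundance column as divided by length, as its header says, would put CDC19 at -1.14 and TYS1 at -0.82, move PGK1, ENO2, TDH3, ADH1 and FBA1 from above 0 to below it, and put RPL41B at 2.33. Subtracting a smooth trend on length would put the chaperones (0.43) and synthetases (0.14) above the median gene and the mitochondrial ribosomal proteins (-0.16) below it.

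**Figure D4:**
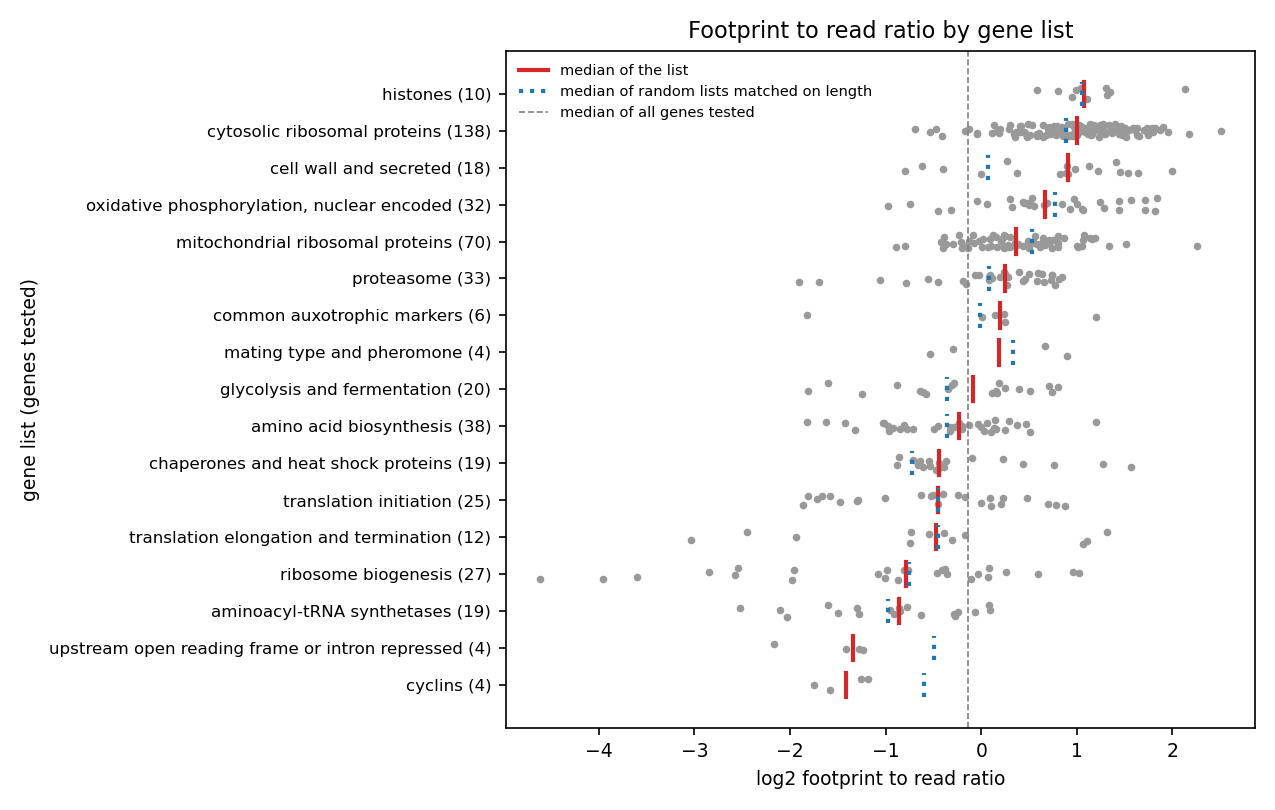
log2 footprint to read ratio (horizontal axis) of the tested members of 17 gene lists, 1 point per gene, with the number tested in brackets. Solid bars are list medians, dotted bars the medians of random lists matched on coding length, and the dashed line the median of all genes tested. Cell wall and secreted proteins (0.90) stand above and cyclins (-1.42) below their length-matched lists.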

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

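Settings other than scaling by the median gene, lower count minimums, pooled counts, 1000 counts and the 99th percentile were chosen after the data were seen, and the smooth trend on length replaced a straight line after the latter's list results were known. No paired analysis was possible because each group has 1 library, and leaving out a library was impossible for the same reason. Leaving out the first and last codons or the highest position, neighbouring codons, division by RNA values, profiles along the frame and evenness were not run, for want of positions and RNA counts per codon. Leaving out stop codons, the top codon of each gene, overlapping or near-identical genes kept the SD of the log2 ratio and its rho with length within their intervals. Scaling by the median gene shifts every log2 ratio alike, so it could not change the SD, the rho or the place of a list. From 4 to 7 of 17 lists lay outside the middle 95% of random lists in all settings. Which lists these were did change: matched on length they were cell wall and ribosomal proteins (high) and cyclins and genes with upstream frames (low). With the smooth trend they were cell wall proteins, chaperones and auxotrophic markers (high) and cyclins, genes with upstream frames and mitochondrial ribosomal proteins (low), and the straight line had the proteasome in place of the markers and added mating genes (low). With 30 counts or no minimum, mitochondrial ribosomal proteins joined the lists that were high (percentile 100). With the abundance taken as divided by length, mating genes (98.2) were high, synthetases (2.40) low, and cell wall proteins inside (97.0). With 30 counts and with no minimum, the SD was 1.22 and 1.24, rho -0.828 and -0.818, and the chaperones lay 0.016 and 0.054 above the median gene. With the abundance column taken as divided by length, the SD was 2.00 and rho -0.963, and log2 ratios changed sign for RPL41B (2.33), TYS1 (-0.82), CDC19 (-1.14), TDH3 (-0.50), PGK1 (-0.74), ENO2 (-0.66), ADH1 (-0.22) and FBA1 (-0.060), by the division itself. Relative to the median gene, the smooth trend turned mitochondrial ribosomal proteins (-0.16), synthetases (0.14) and chaperones (0.43). The straight line turned the same lists (-0.11, 0.052 and 0.35) and the histones (-0.064).

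Pooling was run over all 4579 listed genes, without the count minimums, and not over the tested genes alone. It gave a fold of 12.6 between the highest and lowest sense codon and a preferred-codon difference of 0.957. CGA was at 0.593, CTG 0.845, CGG 0.463, CCC 0.837, GTC 1.96, TTC 1.04 and GTT 1.21. The CGN list was then at -0.20 against other codons, the G34 C forms at 0.230, and the inosine T and C forms at 0.579 and 0.649, with C minus T at 0.490 (G34) and 0.0631 (inosine). The fold was 6.60 with 1000 counts, 6.74 with the 99th percentile cap, 6.97 with each footprint weighing the same, 3.35 with the 90th percentile cap and 4.58 for medians over genes. The preferred-codon difference under these was -0.542, -0.508, -0.513, -0.251 and -0.285, and -0.598 with every gene. The G34 difference was 0.253 with 1000 counts, 0.260 weighing footprints and 0.134 with the 90th percentile cap. The inosine difference was 0.0601 under that cap and 0.0370 for medians, and 0.0542 without the arginine pair. Medians cover 55 sense codons, in genes with 1000 or more counts and 5 or more occurrences of the codon. Over the same codons, but all 2939 genes, the main fold is 4.21 and the main preferred-codon difference -0.348. Medians were not used for lists with a member among the other 6 codons, such as CGN. Where no construction is named, the cause was not tested. Over all alternatives, 387 of 508 values of named genes stayed within their counting intervals and 113 moved beyond them without a reversed call. The lower count minimums and leaving out overlapping or near-identical genes do not change the ratio of a gene that stays. Values under those settings could not move, so the 387 are no measure of robustness. For gene lists 118 of 187 values moved by less than their resampling error and 60 by more, for codons 41 of 114 and 66, and for codon lists 28 of 74 and 42, besides the reversals given. Depth limits single codons, since 40.4% of pairs of gene and codon held no footprint.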

Other observations

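Single codons of abundant genes, chosen after their values were seen, held large shares of a gene's footprints. The only GTG of RPS20, a small subunit ribosomal protein, took 5268 of 16903 footprints (31.2%), 38.0 times the mean codon of the gene. In TEF1, translation elongation factor 1-alpha, the single GTG stood at 71.1 times the gene mean and the stop codon at 43.5. The single GGA of ATP2, the beta subunit of the mitochondrial ATP synthase, stood at 64.5. The single GGA of the ADP-ribosylation factor genes ARF1 and ARF2 stood at 27.1 and 23.7, and the stop codon of the chaperone YDJ1 at 36.1. RPP2B, an acidic ribosomal stalk protein, had 15.4% of its footprints on 1 AAA codon. Tryptophan, with its single codon TGG, averaged 1.48 (1.41 to 1.54), and methionine ATG 0.849 (0.813 to 0.887).

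Stop codons also differed by gene length. Here the stop codon footprints of a length class were divided by the sum of its gene means. Genes with more footprints thus weigh more than in the stop codon values given above. By this measure stop codons stood at 2.08 (1.40 to 2.90 over genes) in genes of up to 100 codons, 2.84 to 200, 3.52 to 300, 4.65 to 500, 3.54 to 1000 and 7.83 (5.55 to 10.3) above 1000 codons. Over the 61 sense codons the codon value had a Spearman rho of -0.677 with how often the codon occurs in all listed genes. Its rho with the number of G and C bases was 0.671. Genes with a near-identical partner lay at a median of -0.21 (-0.35 to 0.14) from the smooth trend on length, and the other genes at 0.02.

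Of the tests that follow, those of the length relation, of near-identical genes and of the ribosomal site were chosen after the results were seen. The 90th percentile cap was also added after the data were seen, but before its own result was known. The ratio of footprints to reads was lower in longer genes. Division of the abundance values by length would raise the ratio of longer genes, so it could not give this pattern. With the column taken as divided, rho was -0.963. That 100% of the values are whole multiples of a single step bears only on how the column was scaled. Loss of footprints towards the end of the frame would lower the stop codon value in long genes. With footprints and gene means summed over genes, it was instead 2.97 times as high in genes above 1000 codons as in those under 200 (2.10 to 4.27). Extra footprints near the start would flatten the relation in long genes, where the slope was instead -1.34 per doubling above 500 codons, and the minimum of 25 footprints in the table is argued against by a rho of -0.911 (-0.930 to -0.888) among the 802 genes with at least 5000 reads, chosen by reads alone, where that minimum reaches only ratios up to 0.0284. Lower recovery of footprints from long mRNAs in the 80S fraction, an abundance column not made from the total RNA library and less initiation on long mRNAs were not tested and stay open.

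Preferred codons held fewer footprints per occurrence. GC content as the whole cause is argued against, as preferred codons lay 0.342 lower than other codons with the same number of G and C bases (a difference of -0.342, -0.358 to -0.326). High counts in a part of the gene and codon pairs may account for a part of it. With pairs capped at the 90th percentile 43.9% of the difference was left, at -0.251, still below 0. The cap can also cut the more variable values of codons that occur rarely in a gene, so it cannot show how large that part is. In the genes they cover, the medians over genes argue against high counts as the whole cause, at -0.285 over 55 codons. These medians cover only genes with 1000 or more counts and 5 or more occurrences of the codon. The means over the same codons, at -0.348, use all 2939 genes, so the values also differ in gene set. The 99th percentile cap left -0.508 of -0.572. Whether such high counts are slow codons or unevenly amplified or ligated fragments was not tested, and no RNA value per codon was used to tell them apart.

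Very high single codons may in part come from reads shared between near-identical genes. Of the 50 highest single-occurrence codons, 10 lay in 7 genes with such a partner (TEF1, TEF2, RPL4A, RPL4B, RPS6A, RPS6B and RPL11B), 5 of them in TEF1 and TEF2. This is 20% (10.03 to 33.7, an exact binomial interval that is too narrow because codons of a gene are not independent) against 3.92% of all single-occurrence codons. Counted by gene family, 4 of 43 families (9.30%, 2.59 to 22.1, exact binomial interval) had near-identical members, against 2.37% of the 548 families with such codons, which is too few to decide. RPS20 and ATP2 have no near-identical partner among the listed genes, but neither shorter shared stretches nor a biological explanation was tested.

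A hypothesis on the ribosomal site is that the deposited codon is the one in the A site, where a stop codon waits for release factors and a start codon is never placed. The stop codon value of 4.49 over all stop codons (4.22 to 4.78) prompted the idea and so is no test of it, and the A site stays untested. The P site, where the start codon sits during initiation, is argued against by the start codon value of 0.0561. A site further downstream, or a rule that left out reads near the start, was not tested.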
